A study of Homo sapiens with 6 samples.

How the data were processed

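RNA sequencing libraries were made from H1299 cells, an established human non-small cell lung cancer line, in which MLST8 had been knocked out and then put back as the wild-type protein or as the E303D mutant. There were 3 libraries per group, 6 in all, from untreated cells grown in serum-containing medium. The groups and replicate numbers were taken from the sample titles, with the wild type as the control, per the labels. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

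The deposited table held FPKM values (fragments per kilobase of exon scaled by depth) that the authors made, for 32655 Ensembl gene identifiers in each library. Per the submitters' processing notes, HISAT2 2.1.0, Bowtie2 2.2.3, TopHat2 and HTSeq 0.6.0 were named with the genome build hg38, and their order and roles are not given in the sources used here. Whether counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. All per-sample columns of the table were used.

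Gene symbols came from a name table that paired 32153 of the identifiers, and positions and biotypes from GENCODE 29 on the same build, which held 32394. FPKM values multiplied by exon length and library total give read numbers. With GENCODE 29 exon lengths they were whole, within 0.050 of a read, for 93.1% of the 31118 genes above 0. For the other 2159 genes the smallest length that gave whole reads was inferred from the values themselves. That length was searched with a tolerance that was widened after a first, narrower one had left some genes unsolved, and it can understate a gene's reads. The library totals obtained in this way were 19184495, 18260960 and 17450859 reads for mLST8-WT and 19241134, 15485012 and 19188527 for mLST8-E303D. The recovered reads summed to between 99.8% and 99.9% of each total. Recovered reads gave the depth, the chi-square and the variation beyond counting, the shares of reads by gene class, the numbers of genes at equal depth, the olfactory receptor ratio and an added alternative, so the limit on inferred lengths applies to these, and not to the main test. At these depths 3 reads, the floor used here, correspond to at most 0.194 FPKM for a gene with 1 kilobase of exon. Floors and the exact interval of the olfactory receptor ratio cover counting error only.

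The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), comparing mLST8-E303D with mLST8-WT over all 6 libraries. Genes needed a mean of at least 1 FPKM, which left 13047, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, while ratios are of mean FPKM. There were 36 gene lists and 5 sets of cell type markers, fixed before the data were examined together with the tests and the alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 35 lists. They were tested again with an estimated correlation and with fry. The fry p-value asks whether the genes of a list move one way on balance, and compares no list with other genes. With an estimated correlation camera also uses fewer degrees of freedom, so a call can be lost without a higher correlation. Named genes were MLST8, then the 12 largest increases and 12 largest decreases among genes past the threshold with a symbol, a mean of at least 5 FPKM in a group and no overlap between groups. Up to 4 members per list past the threshold, by smallest p, were added. Other members are named where 5 or fewer moved against their list, and those were chosen after their values were seen. Some genes that these rules would name are not reported here.

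The alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, rescaling to TPM, median-of-ratios factors, quantile normalization, limma without the trend, robust limma, the replicate number as a block, leaving out each library, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. Added after the data were seen were limma voom on the recovered reads, list counts with voom and without mLST8-WT replicate 3, and 12 further gene groups tested as 1 family. For 2 of those groups, quiescence-associated genes and RNAs listed as nuclear-retained, the predictions were written before the groups were tested. The patterns that those predictions address had already been seen. Of the 14 quiescence-associated genes, 8 also stand in the fixed lists, so their values may have been seen. Intervals of medians are 95% percentile intervals from 10000 resamples of the members, which are not independent of each other, and reflect the spread between genes.

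The tests were run first on simulated data. With 200 of 13047 genes changed between simulated mLST8-E303D and mLST8-WT libraries, 44% of those changed 1.25-fold, 78% of those changed 1.5-fold, 88% of those changed 2-fold and all of those changed 4-fold were recovered, and 4.32% of the calls were unchanged genes. The simulated genes varied independently, with the same dispersion for all genes and both groups. In the data the estimated median dispersion was 0.00226 within mLST8-WT and 6.58e-05 within mLST8-E303D, both of which run low with 3 libraries. Genes of some lists were correlated. Far more than 200 genes were also called, so the simulated shares need not hold for the data. Further software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. List members and markers with no value in the table are not analysed here.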

Results

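RNA was sequenced from MLST8-knockout H1299 lung cancer cells carrying wild-type mLST8 (3 libraries) or mLST8 E303D (3 libraries). mLST8 is a subunit shared by the mTOR complexes, kinases that couple growth to nutrients and growth factors. Depth ran from 15485012 to 19241134 reads per library. The first principal component carried 75.8% of the variance and separated the groups. The second carried 9.6% and set mLST8-WT replicate 3, at -17.1, apart from mLST8-WT replicates 1 and 2, at 9.81 and 8.07. Beyond counting error, well-covered genes varied by an estimated median of 4.76% within mLST8-WT and 0.811% within mLST8-E303D. A median of estimates from 3 libraries runs low, most of all where the variation is small. The size of the contrast between the groups is therefore uncertain. No pair of libraries agreed within sampling noise, with a chi-square per gene of at least 1.59.

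MLST8 was transcribed at a high level in every library and was lower in mLST8-E303D. It lies on hg38 chromosome 16, 2204248 to 2209416, and its identifier is ENSG00000167965. FPKM values were 462, 468 and 426 in mLST8-WT and 336, 326 and 327 in mLST8-E303D, from 21840 to 38340 reads per library. The means were 452 ± 22.7 and 330.0 ± 5.6 FPKM (SD, n = 3 each), a log2 fold change of -0.45 ± 0.04 (SE, limma adjusted p = 1.48e-04). An exact two-sided permutation test gave p = 0.10, the smallest that 3 against 3 allows. These values sum the introduced and any remaining endogenous transcript, and gene-level values cannot show the E303D codon.

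**Figure D1:**
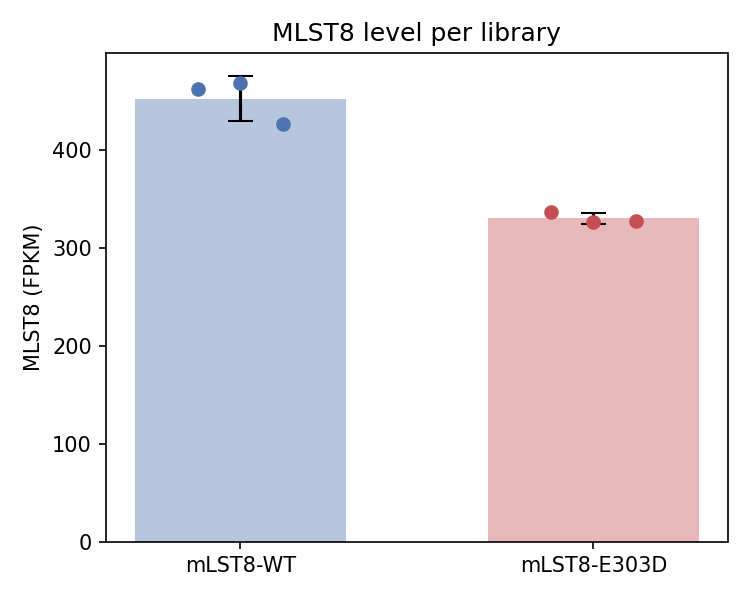
MLST8 level in FPKM (vertical axis) for mLST8-WT and mLST8-E303D. Bars are means, error bars SD and points the 3 libraries of each group; all mLST8-E303D libraries, at most 336 FPKM, lie below all mLST8-WT libraries, at least 426 FPKM.

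Cells with mLST8 E303D had higher transcript levels of mitotic genes than cells with the wild type. CDC20, an activator of the anaphase-promoting complex, rose from 32.9 ± 2.46 to 168 ± 1.28 FPKM (SD, n = 3 each), a 5.11-fold difference. TNC, which encodes the matrix protein tenascin C, fell from 23.5 ± 1.9 to 3.29 ± 0.174 FPKM, a 7.13-fold difference. Of 13047 genes tested, 7217 passed the threshold by limma, 3259 higher and 3958 lower in mLST8-E303D. Most changes were small: 4814 of those genes differed by less than 0.5 in log2, and 455 by at least 1, of which 233 were higher and 222 lower. The groups did not overlap in 8350 genes (64%), where chance gives 10%. With median-of-ratios factors the calls split into 4154 higher and 3084 lower, against 3259 and 3958 as deposited.

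The 12 largest increases were in DKK1, CDC20, PLK1, KIF20A, CCNB1, MYBL2, CENPA, MKI67, ERRFI1, DLGAP5, TFRC and BIRC5. DKK1 (hg38 chromosome 10, 52314296 to 52318042), a secreted WNT antagonist, rose from 0.948 ± 0.0418 to 9.11 ± 0.31 FPKM, with a log2 fold change of 2.38 ± 0.05 (SE, limma adjusted p = 3.18e-07). PLK1 (hg38 chromosome 16, 23677656 to 23690367), a mitotic kinase, rose from 6.85 ± 0.123 to 37.9 ± 1.13 FPKM. The proliferation antigen gene MKI67 rose from 9.24 ± 0.991 to 40.4 ± 1.13 FPKM. ERRFI1, a feedback inhibitor of EGFR, rose from 85.1 ± 2.81 to 340.3 ± 3.02 FPKM. TFRC, the transferrin receptor, had a log2 fold change of 1.83 ± 0.06. In each of the 12, every mLST8-E303D library lay above every mLST8-WT library, as the rule that chose them required. The smallest of the 12 increases, in BIRC5, was 1.82 ± 0.04 in log2.

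Decreases were largest in TNC, SPX, MALAT1, SAT1, APOE, LAMP3, TIMP1, TRAPPC6A, LINC01419, CCDC18-AS1, BCAM and EPB41L4A-AS1. TNC (hg38 chromosome 9, 115019578 to 115118257) had a log2 fold change of -2.51 ± 0.07 (SE, limma adjusted p = 4.36e-07). MALAT1 (hg38 chromosome 11, 65497688 to 65506516), a nuclear long non-coding RNA, fell from 172 ± 25.8 to 30.2 ± 1.2 FPKM. SAT1, which catalyses polyamine acetylation, fell from 129.6 ± 6.97 to 29.3 ± 0.484 FPKM. The lipid carrier gene APOE fell from 78.5 ± 8.12 to 19.3 ± 1.52 FPKM. TIMP1, an inhibitor of matrix metalloproteinases, fell from 351 ± 31.3 to 93.9 ± 3.33 FPKM. In each of the 12, every mLST8-E303D library lay below every mLST8-WT library, as the same rule required. Long non-coding genes took 1.54% of reads in mLST8-WT and 1.08% in mLST8-E303D, pseudogenes 1.1% and 0.926%, and mitochondrial ribosomal RNA 0.584% and 0.192%. Values of the antisense genes CCDC18-AS1 and EPB41L4A-AS1 are uncertain, since reads of the opposite strand could not be told apart.

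**Figure D2:**
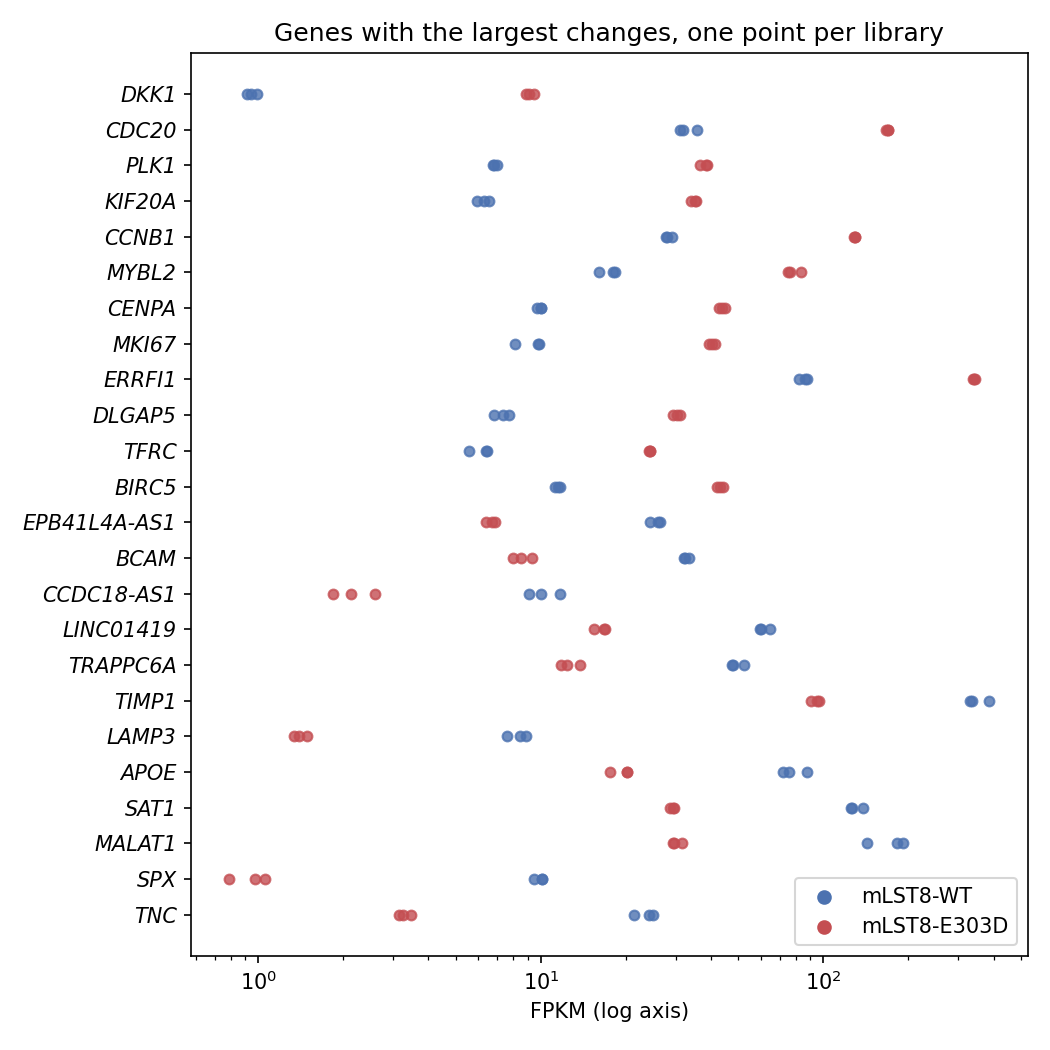
FPKM on a log axis (horizontal) of the 12 genes with the largest increases and the 12 with the largest decreases in mLST8-E303D, 1 gene per line and 1 point per library. No gene's mLST8-WT and mLST8-E303D points overlap, which the choice of genes required. DKK1 had 0.948 FPKM on average in mLST8-WT and 9.11 in mLST8-E303D.

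Most cell cycle genes rose. Of 43 G2/M genes tested, 43 rose, 0 fell and 0 did not pass (43 and 0 adjusted over the list alone), with a median log2 fold change of 1.53 (camera adjusted p = 7.85e-30, and 0.00685 with an estimated correlation). CCNB1, the mitotic cyclin B1, rose from 28.2 ± 0.806 to 129 ± 0.645 FPKM and CENPA, the centromeric histone H3 variant, from 9.93 ± 0.197 to 43.7 ± 1.03. Among 46 genes of G1/S and DNA replication, 43 rose, 1 fell and 2 did not pass (43 and 2 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 4.98e-18, 0.00725 with an estimated correlation). MCM4 and MCM7, subunits of the replicative helicase, rose from 27.6 ± 0.21 to 63.9 ± 0.795 and from 70.9 ± 2.48 to 166 ± 1.83 FPKM. The gene that fell was CCND2, a D-type cyclin, with a log2 fold change of -1.03, and without mLST8-WT replicate 3 there were 2 such genes. In nucleotide synthesis, 20 rose, 0 fell and 5 did not pass of 25 (22 and 1 adjusted over the list alone; camera adjusted p = 5.84e-08, 0.0265 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, rose from 20.6 ± 0.917 to 71 ± 0.569 FPKM, and CTPS1, a CTP synthase, from 11 ± 0.312 to 22.6 ± 0.427. Of 12 replication-dependent histone genes, 8 rose, 4 fell and 0 did not pass (8 and 4 adjusted over the list alone, camera adjusted p = 0.0521). Their near-identical copies make single values uncertain. Their transcripts are mostly not polyadenylated, so the values also depend on how RNA was selected, which was not tested. H1-2 rose from 19.3 ± 0.724 to 62.9 ± 3.26 FPKM, while H2BC8 had a log2 fold change of -0.61, and H2BC4, H2BC5 and H2BC21 also fell. The histone list passed by camera without mLST8-WT replicate 2 (adjusted p = 0.0405), mLST8-WT replicate 3 (0.0442), mLST8-E303D replicate 2 (0.0388) or mLST8-E303D replicate 3 (0.047). It also passed with no filter (0.00125, camera adjusted p) and with limma voom on the recovered reads (0.0366), in a range of 0.00125 to 0.0949 over the processing alternatives at the preset correlation.

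Most genes for building ribosomes rose, while most genes that encode ribosomal proteins fell. In the list of ribosome biogenesis and MYC, 29 rose, 1 fell and 11 did not pass of 41 (29 and 1 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 5.08e-09, 0.0265 with an estimated correlation). MYC, a transcription factor that drives growth, rose from 53.9 ± 1.1 to 122 ± 3.19 FPKM, and NCL, the nucleolar protein nucleolin, from 71.4 ± 1.9 to 120.3 ± 0.324, while RRP12 fell. Of 78 cytosolic ribosomal protein genes, 3 rose, 66 fell and 9 did not pass (3 and 66 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 1.59e-10). The call was lost at adjusted p = 0.518 with an estimated correlation. RPS18 fell from 1186 ± 88.4 to 634 ± 0.582 FPKM and RPL39 from 216 ± 19 to 126 ± 1.54, and both have processed pseudogenes that can share reads. RPS23, RPS26 and RPSA rose, and without mLST8-WT replicate 3 there were 5 such genes. Mitochondrial ribosomal RNA made up 0.584% of reads in mLST8-WT and 0.192% in mLST8-E303D. For translation initiation and elongation, 14 rose, 12 fell and 12 did not pass of 38 (15 and 14 adjusted over the list alone; camera adjusted p = 0.688), with EIF4A2 at a log2 fold change of -0.65 ± 0.03 and EIF3B at 0.58 ± 0.03.

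Most stress response genes of the endoplasmic reticulum and of amino acid limitation fell. Of 24 genes of the unfolded protein response, 0 rose, 18 fell and 6 did not pass (0 and 19 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 8.13e-06, 0.0411 with an estimated correlation). HSPA5, the chaperone BiP, fell from 390.1 ± 5.56 to 138 ± 1.89 FPKM and CALR, calreticulin, from 303 ± 10.5 to 174 ± 1.57; without mLST8-WT replicate 3, 1 member rose. Of 43 ATF4 targets, 7 rose, 27 fell and 9 did not pass (7 and 27 adjusted over the list alone; camera adjusted p = 8.21e-05, but adjusted p = 0.0745 with an estimated correlation). TRIB3, a pseudokinase induced by stress, fell from 89.9 ± 3.07 to 26.7 ± 0.669 FPKM and ASNS, asparagine synthetase, from 257 ± 6.58 to 121 ± 1.22. In the heat shock response, 10 rose, 5 fell and 4 did not pass of 19 (11 and 5 adjusted over the list alone; camera adjusted p = 0.084). HSPA1A fell from 38.9 ± 1.82 to 12.6 ± 0.338 FPKM and HSP90AA1 rose from 385 ± 11.8 to 805 ± 9.81. HSPA1A and HSPA1B are near-identical copies, so the split between them is uncertain, and DNAJB1, DNAJB4 and BAG3 were the other members that fell. The heat shock list passed by camera without mLST8-WT replicate 3 (adjusted p = 0.0263) and with no filter (0.0184), in a range of 0.0184 to 0.362 over the processing alternatives at the preset correlation.

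Of 33 proteasome genes, 21 rose, 1 fell and 11 did not pass (22 and 2 adjusted over the list alone; camera adjusted p = 6.92e-05, but adjusted p = 0.442 with an estimated correlation). PSMD1 rose from 30.9 ± 0.681 to 44.3 ± 0.448 FPKM, and PSME1, an activator subunit, fell; the number that fell was 2 without mLST8-WT replicate 3 and 2 with limma voom. Of 44 genes of lysosome and autophagy, 5 rose, 24 fell and 15 did not pass (5 and 24 adjusted over the list alone; camera adjusted p = 0.0112, but adjusted p = 0.292 with an estimated correlation). GAA, the lysosomal alpha-glucosidase, fell from 34 ± 0.516 to 13.8 ± 0.282 FPKM and MAP1LC3B, an autophagosome protein, from 74 ± 2.97 to 38.4 ± 0.296. SQSTM1, NPC1, NPC2 and ATP6V0A1 were among those that rose, and without mLST8-WT replicate 3 the number that rose was 10.

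Metabolic lists were mixed. In glycolysis, 14 rose, 3 fell and 5 did not pass of 22 (14 and 3 adjusted over the list alone; camera adjusted p = 3.94e-04, but adjusted p = 0.327 with an estimated correlation). PKM, pyruvate kinase, rose from 85.5 ± 1.73 to 207 ± 0.353 FPKM and LDHA, lactate dehydrogenase A, from 60.6 ± 2.05 to 106 ± 0.898, while SLC2A3, ENO2 and SLC16A1 fell. In cholesterol synthesis, 13 rose, 4 fell and 7 did not pass of 24 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0349, but adjusted p = 0.255 with an estimated correlation). Among the members that fell, TM7SF2, a sterol reductase, went from 17.5 ± 0.925 to 8.04 ± 0.188 FPKM, and MSMO1, STARD4 and SREBF2 also fell. The call of cholesterol synthesis was also lost without mLST8-WT replicate 1 (camera adjusted p = 0.0598), with a mean of at least 5 FPKM (0.103) and with quantile normalization (0.185), in a range of 0.0010 to 0.185 over the processing alternatives at the preset correlation. Its median was 0.26 with the settings used throughout, and 0.26, 0.26 and 0.21 under those alternatives. In fatty acid synthesis, 7 rose, 4 fell and 8 did not pass of 19 (7 and 4 adjusted over the list alone; camera adjusted p = 0.70), and SCD, a fatty acid desaturase, fell from 1039 ± 39.1 to 547 ± 4.26 FPKM, with SCD5, ACSS2 and ME1. In the pentose phosphate pathway, 3 rose, 3 fell and 1 did not pass of 7 (3 and 3 adjusted over the list alone; camera adjusted p = 0.703): PGD, RPIA and RPE rose and PGLS, TKT and TALDO1 fell. TKT no longer passed without any 1 mLST8-E303D library, with log2 fold changes of -0.14, -0.14 and -0.13, nor with median-of-ratios factors (-0.05). ENO2 was lost without mLST8-WT replicate 2 (-0.13), mLST8-E303D replicate 1 (-0.16) or replicate 3 (-0.15), with median-of-ratios factors (-0.09) and on the TPM scale (-0.12). Of 47 nuclear genes of the respiratory chain, 12 rose, 13 fell and 22 did not pass (11 and 12 adjusted over the list alone; camera adjusted p = 0.725), with SDHA at a log2 fold change of -0.32 ± 0.04. Of 13 mitochondrial ones, 3 rose, 3 fell and 7 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.993). MT-CYB rose from 1789 ± 109 to 2751 ± 102 FPKM, with MT-ND2 and MT-ATP6, and MT-CO1 fell from 7689.9 ± 392 to 5329 ± 38.9, with MT-ND1 and MT-ND5; without mLST8-WT replicate 3, 6 rose and 4 fell, and with limma voom 4 rose and 6 fell. MT-CO1 no longer passed when no filter was applied, with a log2 fold change of -0.53.

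Of 20 YAP/TEAD targets, 15 rose, 1 fell and 4 did not pass (15 and 2 adjusted over the list alone; camera adjusted p = 8.35e-05, but adjusted p = 0.0745 with an estimated correlation). ANKRD1 rose from 4.99 ± 0.194 to 19.9 ± 0.878 FPKM and CCN1 from 209 ± 7.41 to 409 ± 2.05, and GADD45A fell; the number that fell was 2 without mLST8-WT replicate 3 and 2 with limma voom. Of 27 RAS-ERK feedback and early genes, 14 rose, 3 fell and 10 did not pass (14 and 3 adjusted over the list alone; camera adjusted p = 0.0124, but adjusted p = 0.151 with an estimated correlation). FOSL1 and DUSP5 rose, by 0.75 and 0.81 in log2, while DUSP6, a phosphatase that acts on ERK, fell from 20.03 ± 0.78 to 11.8 ± 0.123 FPKM, with JUNB and KLF10. The call of RAS-ERK feedback and early genes was also lost with a mean of at least 5 FPKM, where the median was 0.14 against 0.14 (camera adjusted p = 0.0878, in a range of 4.56e-04 to 0.0878 over the processing alternatives at the preset correlation).

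Of 12 antigen presentation genes, 1 rose, 9 fell and 2 did not pass (1 and 10 adjusted over the list alone; camera adjusted p = 0.00275, but adjusted p = 0.255 with an estimated correlation). HLA-B fell from 34.7 ± 2.52 to 15 ± 0.239 FPKM and HLA-C from 24.3 ± 1.61 to 11 ± 0.0392, both members of a family of similar sequences, and TAP2 rose. In the interferon response, 1 rose, 16 fell and 6 did not pass of 23 (2 and 16 adjusted over the list alone; camera adjusted p = 0.00289, but adjusted p = 0.238 with an estimated correlation). IFI6 fell from 30.3 ± 0.808 to 16.4 ± 1.64 FPKM and ISG15, a ubiquitin-like modifier, from 77.5 ± 7.83 to 47.2 ± 0.874, while OAS3 rose; without mLST8-WT replicate 3 the number that rose was 2. The call of this list was also lost with a mean of at least 5 FPKM, where its median was -0.23 and camera gave adjusted p = 0.0961, in a range of 1.18e-04 to 0.0961 over the processing alternatives at the preset correlation. In invasion and proteases, 5 rose, 15 fell and 5 did not pass of 25 (5 and 15 adjusted over the list alone; camera adjusted p = 0.00833, but adjusted p = 0.151 with an estimated correlation). MMP14, a membrane metalloproteinase, fell from 142 ± 0.626 to 65 ± 0.495 FPKM and MMP2 from 4.74 ± 0.213 to 1.31 ± 0.0325; PLAU, ADAM9, ITGA6, ITGB5 and CD44 rose. Of 22 mesenchymal and TGF-beta response genes, 4 rose, 12 fell and 6 did not pass (5 and 12 adjusted over the list alone; camera adjusted p = 0.0711), with COL6A2 falling from 21.7 ± 0.175 to 11.1 ± 0.577 FPKM and VIM, CDH2, SMAD3 and LOXL2 rising. That list passed by camera without mLST8-WT replicate 2 (adjusted p = 0.0428), with no filter (0.0476), on the TPM scale (0.0432) and with median-of-ratios factors (0.039), in a range of 0.039 to 0.105 over the processing alternatives at the preset correlation.

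**Figure D3:**
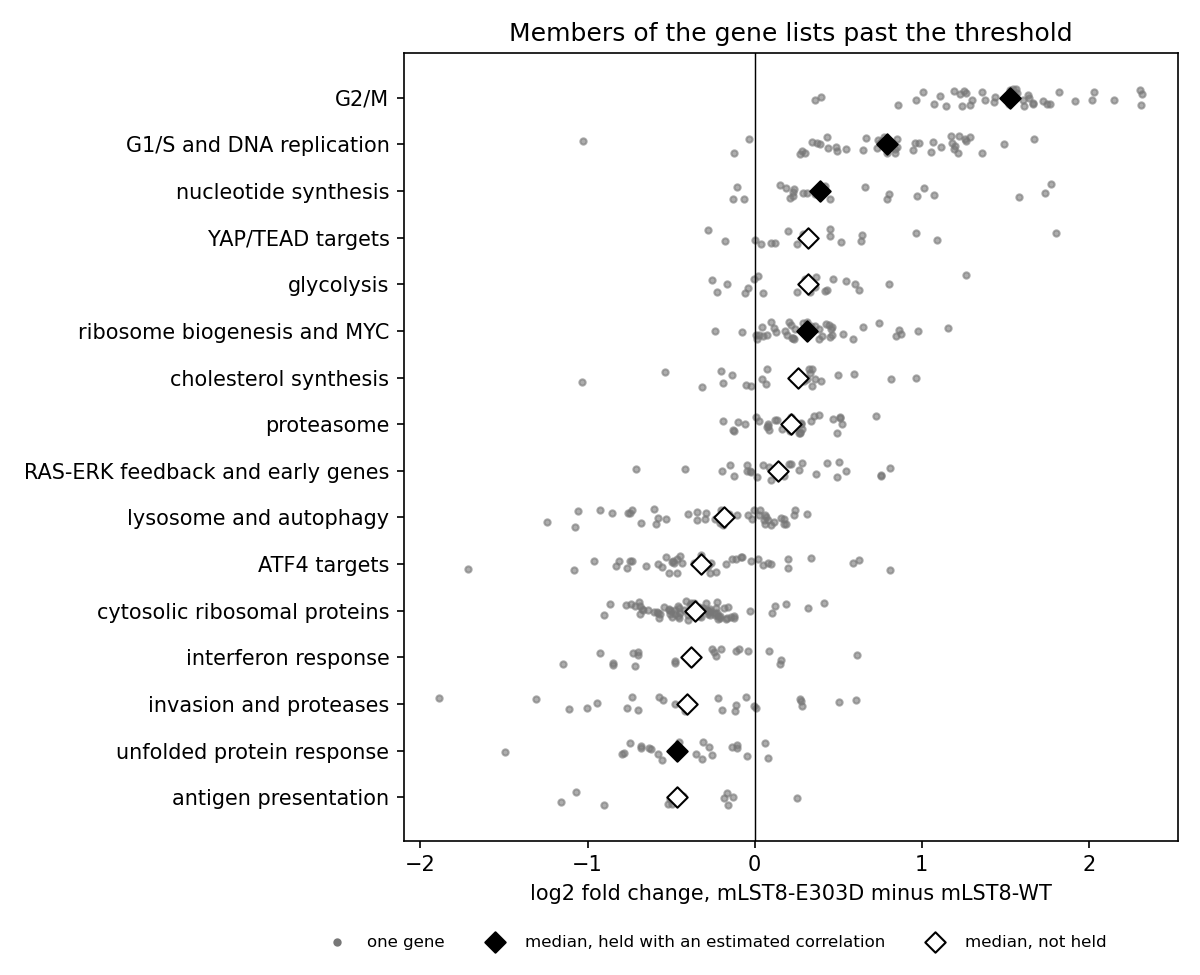
Log2 fold change, mLST8-E303D minus mLST8-WT (horizontal axis), of each tested member of the 16 gene lists past the camera threshold. Grey points are genes and diamonds list medians, black for the 5 lists whose call held with an estimated correlation; the G2/M median is 1.53.

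Components and readouts of mTOR signalling moved in both directions. Of 10 mTOR complex subunits, 5 rose, 3 fell and 2 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.548). MAPKAP1, an mTORC2 subunit, rose from 64.4 ± 2.03 to 85.4 ± 0.363 FPKM, with MTOR, AKT1S1, TELO2 and TTI1. DEPTOR, an mTOR inhibitor, fell from 2.2 ± 0.191 to 0.917 ± 0.141 FPKM, with MLST8 and TTI2. Among 33 upstream regulators of mTORC1, 8 rose, 12 fell and 13 did not pass (8 and 12 adjusted over the list alone; camera adjusted p = 0.455), and 5 rose without mLST8-WT replicate 3. SESN2 and DDIT4, stress-induced inhibitors of mTORC1, fell from 53 ± 1.49 to 30.8 ± 0.375 and from 84.3 ± 1.67 to 47 ± 1.98 FPKM. For the AKT and SGK axis, 9 rose, 2 fell and 10 did not pass of 21 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0869). SGK1, a kinase activated by mTORC2, rose from 1.93 ± 0.0562 to 3.65 ± 0.236 FPKM; without mLST8-WT replicate 3 the number that fell was 4. Of 26 FOXO targets, 6 rose, 12 fell and 8 did not pass (6 and 12 adjusted over the list alone; camera adjusted p = 0.386), with KLF6 rising from 16.5 ± 0.643 to 48.7 ± 0.971 FPKM and CDKN1A falling from 53.2 ± 1.47 to 30.8 ± 0.828.

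The remaining lists did not pass. Camera gave adjusted p = 0.119 for the hypoxia response (4 rose, 10 fell and 5 did not pass of 19; 4 and 10 adjusted over the list alone), where VEGFA had a log2 fold change of -0.69 ± 0.05 and ADM, EGLN1, STC1 and HIF1A rose. Among 20 p53 targets, 6 rose, 8 fell and 6 did not pass (6 and 8 adjusted over the list alone; camera adjusted p = 0.522), and TNFRSF10B fell from 39.6 ± 1.37 to 18.9 ± 0.435 FPKM. NRF2 targets gave 0.604 (camera adjusted p; 2 rose, 5 fell and 14 did not pass of 21; 2 and 5 adjusted over the list alone): SLC7A11 and KEAP1 rose, NQO1, ABCC3, ME1, FTH1 and FTL fell, and 4 rose without mLST8-WT replicate 3. Epithelial genes gave 0.38 (camera adjusted p; 2 rose, 5 fell and 5 did not pass of 12; 2 and 5 adjusted over the list alone): KRT18 and DSP rose and CLDN1, CLDN4, CDS1, JUP and SPINT2 fell. Notch genes gave 0.386 (camera adjusted p; 2 rose, 5 fell and 6 did not pass of 13; 2 and 5 adjusted over the list alone): HES4 and NRARP rose, HEY1, HEYL, NOTCH3, JAG1 and DTX3 fell, and 1 rose without mLST8-WT replicate 3. WNT targets gave 0.604 (camera adjusted p; 4 rose, 3 fell and 5 did not pass of 12; 4 and 3 adjusted over the list alone): DKK1, TCF7, WNT5B and FZD1 rose and NOTUM, SFRP1 and FZD7 fell. SFRP1 no longer passed without mLST8-E303D replicate 1 (log2 fold change -0.17) or with median-of-ratios factors (-0.13). NF-kB and cytokine genes gave 0.995 (camera adjusted p; 4 rose, 4 fell and 4 did not pass of 12; 4 and 4 adjusted over the list alone): NFKB1, NFKB2, LIF and IRAK2 rose and ICAM1, CSF1, NFKBIA and BIRC3 fell. The camera direction was higher and the median negative for WNT targets (-0.07, mean 0.19), NF-kB and cytokines (-0.06, mean -0.09), fatty acid synthesis (-0.01, mean -0.03) and the mitochondrial respiratory chain (-0.05, mean 0.03). Under the 3 scaling alternatives the medians of the latter lists, fatty acid synthesis and the mitochondrial respiratory chain, were above 0. Of neuroendocrine genes, 4 were tested, too few for camera, and CHGB and ENO2 fell.

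Most markers of other cell types had low values in both groups. Of 10 blood and immune markers and 9 fibroblast markers in the table, none reached a mean of 1 FPKM in either group. EGFL7 was the endothelial marker of 8 above that level, and fell from 16.7 ± 1.19 to 9.46 ± 0.346 FPKM (limma adjusted p = 4.05e-05). AGER was the lung epithelial marker of 6 above it, with 1.44 ± 0.379 FPKM in mLST8-WT and 0.917 ± 0.15 in mLST8-E303D (limma adjusted p = 0.0689). CDKN2A, of 8 markers of other cell lines, had 36.6 ± 2.6 and 38.7 ± 0.483 FPKM (limma adjusted p = 0.239).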

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

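Limma voom on the recovered reads, and the list counts with voom and without mLST8-WT replicate 3, were chosen after the data were seen. The count of 7217 genes stayed within 1.5 times of itself in all alternatives but that of an absolute log2 fold change of at least 1, where it was 455, a stricter criterion by construction. It ranged from 6112 to 7710 with 1 library left out, was 4907 with a mean of at least 5 FPKM, where fewer genes are tested, and was 7534 with voom. Of the 16 gene lists past the camera threshold, 5 remained past it with an estimated correlation. Leaving out 1 library gave 15 to 18, and fry, which asks another question, passed 28. A call lost with an estimated correlation need not reflect correlated genes, since camera then also uses fewer degrees of freedom. RAS-ERK feedback and early genes lost theirs at an estimated correlation of -0.0085, under the preset 0.01. For cytosolic ribosomal proteins the estimate was 0.89. With a mean of at least 5 FPKM the calls of the interferon response, RAS-ERK feedback and early genes and cholesterol synthesis were lost; the last was also lost with quantile normalization and without mLST8-WT replicate 1, and the cause was not tested. Replication-dependent histones, mesenchymal and TGF-beta response genes and the heat shock response passed under some alternatives only. The log2 fold change of MLST8 lay between -0.49 and -0.37 in all alternatives that refit the data, and stayed past the threshold. MLST8 also met an adjusted p under 0.01, but not an absolute log2 fold change of at least 1. For the 155 other named genes the same refits gave 2618 values. Of these, 2606 kept direction and side of the threshold, 12 kept direction but no longer passed, and 0 reversed. Those 12 belong to TKT, SFRP1, ENO2 and MT-CO1, and the cause was not tested. The 2618 values leave out the stricter criteria of adjusted p and fold change. TKT, ENO2 and SFRP1 did not reach an adjusted p under 0.01 (limma adjusted p = 0.0175, 0.0222 and 0.0139). Named genes with an absolute log2 fold change under 1 did not meet the other criterion. The replicate numbers did not pair the samples: deviations from the group means correlated at -0.03, 0.03 and -0.05 between samples of the same number, and mLST8-WT replicate 1 and mLST8-WT replicate 3 correlated best with a sample of another number. With the replicate number as a block, 6717 genes and 17 lists passed, the further list being replication-dependent histones, and MLST8 stayed past the threshold. Depth sets a floor of at most 0.194 FPKM, or 3 reads, for a gene with 1 kilobase of exon.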

Other observations

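The gene groups of the first paragraph were chosen after the data were seen. So were the test of GC content and length on neighbouring genes and the weighing of medians with their intervals. For quiescence-associated genes and RNAs listed as nuclear-retained, the predictions were written before the groups were tested. Of 24 tested host genes of small nucleolar RNAs, which carry those RNAs in their introns, 14 fell in mLST8-E303D, 3 rose and 7 did not pass, with a median log2 fold change of -0.41. GAS5 fell from 186 ± 9.32 to 54.5 ± 0.846 FPKM (SD, n = 3 each), SNHG32 from 255 ± 9.57 to 87.6 ± 0.689 and SNHG12 from 10.8 ± 0.638 to 3.02 ± 0.338, while DANCR rose from 5.6 ± 0.493 to 13.7 ± 0.373 and SNHG3 and SNHG4 also rose. Among the 12 groups tested as 1 family, camera gave adjusted p = 0.0202 for these genes, and adjusted p = 0.523 with an estimated correlation. Of 1105 long non-coding genes 377 fell and 127 rose (camera adjusted p = 0.0296, and adjusted p = 0.0818 with an estimated correlation). The composition of the libraries moved with these groups: in mLST8-WT and mLST8-E303D, long non-coding genes took 1.54% and 1.08% of reads, pseudogenes 1.1% and 0.926%, and mitochondrial ribosomal RNA 0.584% and 0.192%. Of 29 kinesins 18 rose and 3 fell (camera adjusted p = 8.28e-05, and adjusted p = 0.473 with an estimated correlation), with KIF3A, KIF7 and KIF17 falling. Of these kinesins 5 belong to the G2/M list, and of the other 24, 13 rose and 3 fell. The other 9 groups did not pass: camera adjusted p was 0.321 for quiescence-associated genes, 0.451 for RNAs listed as nuclear-retained, 0.465 for pseudogenes, 0.231 for zinc finger genes, 0.119 for protein-coding genes, 0.636 for solute carriers, 0.803 for keratins, 0.465 for mitochondrial ribosomal proteins and 0.181 for aminoacyl-tRNA synthetases.

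The 7217 genes past the threshold came from 1 of 10 ways to split the 6 libraries into 3 and 3, and each of the other splits gave 0 by limma, with at most 198 genes at an unadjusted p under 0.05 against 7910 for the real split. For gene lists the real split gave 16 and the highest of the others 13. With 10 splits no share under 0.05 can be reached, in either case. In the other splits camera at the preset correlation called 8 to 13 lists. Each of those splits mixes libraries of both groups on each side, so the difference between the groups widens the spread within a side. The mix is unequal, so part of that difference also remains between the sides, where a list test can pick it up. Their counts are therefore no baseline for chance, for genes or for lists.

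Higher cell cycle genes in mLST8-E303D were the largest shift of any list, with a G2/M median of 1.53 (95% interval 1.36 to 1.61). The lowest G2/M median over 3 scaling alternatives was 1.5. It was 1.53 after removing the trends with GC content and length, and 1.55 after subtracting the median of 100 neighbours. Each interval lay above the bound of 1.0 set beforehand. For scaling and neighbours that outcome was all but given. The median of all genes was -0.03 as deposited and at most 0.04 after scaling. The largest absolute median of a run of neighbouring genes was 0.33. Shifts of that size are too small to account for 1.53, and passing the bound adds nothing to this. A faster growth state or lower density of the mLST8-E303D cultures may account for the shift, and would lower quiescence-associated genes. Their median of -0.33 lay just under the bound of -0.3, but its interval ran from -0.55 to 0.14. Of the 14, 8 were lower and 3 higher, and 8 also stand in other lists used here. No value of this median could tell a growth state of the cultures from an effect of E303D itself on growth, since either would lower these genes. Whether the substitution, the lower MLST8 level or a difference between the derived lines underlies the higher cell cycle genes is untested.

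More genes were detected in mLST8-WT, from 24268 to 25249 per library against 23116 to 23862. Depth was not the reason: at equal reads the lowest mLST8-WT library still had 709 more genes than the highest mLST8-E303D library, above the bound of 300 set beforehand. Genomic DNA in the mLST8-WT libraries may contribute. Reads on 80 olfactory receptor genes were, scaled by depth, 1.17 times as many there (exact 95% interval 1.04 to 1.32). That interval lay under the 1.5 set beforehand for genomic DNA as the cause, which argues against a contribution of that size. The interval covers counting error only and was not wholly under 1.2, so a smaller contribution stays open. Nuclear RNA content is open. The 6 RNAs tested as nuclear-retained, without MALAT1, had a median of -0.12 (interval -0.70 to 0.13). They include NORAD and OIP5-AS1, which are known as largely cytoplasmic, so this median decides nothing. NEAT1 (-0.99) and PVT1 (-0.41) were the members that fell.

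Neighbouring genes shifted together in 1 region. Of 11860 runs of 50 neighbouring genes, 7 overlapping ones on hg38 chromosome 19, 16324817 to 18928633, had medians beyond the largest of 100 shuffles (up to 0.33 in absolute value, against 0.29), with 32 of 59 genes lower and 5 higher and a median of -0.27, or -0.16 with the trends of GC content and length removed. A first version of the test, which took 251 runs that do not overlap, found 0, and covering every run was settled on after that result was known. A copy number difference between the derived lines may lie behind the region, but after the trends with GC content and length were removed 0 runs exceeded the shuffles, so GC content and gene length, which were removed together and not separately, are a candidate explanation from which copy number cannot be told apart.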
